A study of Macaca mulatta with 2 samples.

How the data were processed

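RNA from 2 Sertoli cell cultures of Macaca mulatta, 1 pubertal and 1 infant, was compared. Groups were taken from the sample titles. Per the labels' protocols, infant cells came from animals under 3 months old, and pubertal cells from animals that received gonadotropin-releasing hormone through a catheter over 4 to 5 weeks, in pulses of 2 min at 0.15 µg/min with an interval of 3 h. Total RNA was extracted with Trizol and labelled with Cy3 by the Agilent Quick-Amp kit, per the labels' protocols. How many animals were pooled into a culture is not given in the sources used here. Both arrays lay on the same slide with the same scan, per the file headers, so slide and scan do not separate the groups.

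The deposited values are spot intensity values written by Agilent Feature Extraction 10.5.1.1, per the file headers and the submitters' processing notes. Per the file headers, the authors' processed intensity was background-subtracted and corrected for spatial trend within each array, with low values replaced by a surrogate, and no scaling between arrays is recorded. The array design is a human one annotated on hg18, per the file headers. Human probes bind monkey transcripts less well where the sequences differ, which lowers signals in a probe-specific way, and differences between arrays of one probe are less affected than levels. Flags for background, saturation and outliers were used as deposited, with each spot's error estimate. Probe positions were not used here.

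Each array held 52857 spots, of which 51538 were gene spots. Outlier spots, 96 on the pubertal and 91 on the infant array, were left out, and control spots were not used for gene values. The log2 of the processed signal was taken and the 75th percentile of each array (406.7 and 382.4 intensity units) subtracted. Spots of one probe were averaged. A probe counted as detected where at least 50% of its spots were flagged well above background, which held for 62.5% of the gene-annotated probes on the pubertal array and 62.1% on the infant array. A gene took the mean of its probes detected on both arrays. Of the 4766 genes with several such probes, the median SD between probes was 0.21, and 11 of the genes past 2-fold had probes of opposite sign. The error model of the scanner software gave a median error of 0.20 for a gene's difference, which covers the array and not the culture. Gene names are those of the array design, and 14940 of 21492 also occur as names or synonyms in macaque gene tables.

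Before the data were examined, 30 gene lists and 12 cell type marker lists were fixed, together holding 952 gene names, of which 25 are not on the array under that name. A list was described by the median difference of its members detected on both arrays, the number at least 2-fold different, and the percentile of the median among 10000 random lists of the same size, drawn from 20 bins of mean expression. The gap between germ cell and other cell type markers was given a bootstrap interval over markers from 10000 draws, which treats genes as independent and does not cover the culture. With 1 array per group no test between groups was made, and the number of arrays limits the precision. Genes were named by a rule fixed beforehand. It takes the 12 largest differences in each direction among genes with symbols whose probes changed the same way, the 6 largest lower bounds in each direction among genes detected on 1 array, up to 3 members of each list with the largest difference, and 19 Sertoli cell genes whatever their values. Some genes that the rule takes are not given in the text. Other genes named in the text were chosen after their values were seen.

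For a gene detected on 1 array, the fold is a lower bound against the higher of the lowest detected signal of the dim array (-4.29 pubertal, -4.37 infant) and the gene's own signal.

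Alternatives fixed beforehand were normexp background correction with an offset of 50, scaling on the median, quantile normalization, loess normalization with a span of 0.3, the percentile over detected probes alone, no filter on dim probes, a filter at the median signal, the brightest probe or the median of all probes per gene, thresholds of 1.5- and 4-fold, and a weaker detection flag. After the data were seen, scaling on spike-in probes and leaving out disturbed areas were added, and the limits of those areas were set from the spatial pattern of the spots. A spot lay in a disturbed area where at least 2 neighbours within 2.3 grid units differed by over 4 log2 in the same direction, or where the dim neighbours within 4.2 units (at least 6) had a median difference over 1.5 in size. This took 834 spots, 1.58% of each array, some of them without a visible disturbance.

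The gene, count and list functions were tested on simulated data made from the infant array with the noise between replicate spots, for 14242 genes. The noise was taken from probes with every spot well above background on both arrays, so it may be too small for dim genes. Of 67 genes changed 3-fold, 100% passed 2-fold, as did all 66 genes changed 6-fold, and 1.49% of 67 genes changed 1.5-fold. Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, R 4.3.3 with limma 3.58.1, and matplotlib 3.10.9 for the figures.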

Results

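Messenger RNA levels were measured on 2 one-colour oligonucleotide arrays hybridised with RNA from primary cultures of rhesus macaque Sertoli cells, the somatic cells of the seminiferous tubule that support germ cells. One array held a culture from infant testes, taken from males under 3 months old. The other held a culture from males of 18 to 22 months in which puberty had been brought on by pulses of gonadotropin-releasing hormone, given for 4 to 5 weeks. Both cultures had received 100 nM testosterone and 5 ng/ml follicle-stimulating hormone (FSH) for 12 h. The comparison therefore asks how hormone-treated Sertoli cell cultures differ between the infant and the pubertal testis. Each group had 1 array and there was no replicate, so no difference below carries a test. Animal, culture, age and the gonadotropin-releasing hormone treatment cannot be separated. Both arrays carried human probes, to which the monkey RNA had to cross-hybridise.

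On the pubertal array 54.8% of the gene spots were well above background, and on the infant array 54.7%. None was saturated. Of 21492 gene names, 14242 had a probe well above background on both arrays, and their values correlated across genes with r = 0.956. Values are log2 signals relative to the 75th percentile of the array, and differences are pubertal minus infant. Spots of the same probe within an array varied with a median SD of 0.09 on the pubertal array and 0.08 on the infant array. This was measured over 78 replicated probes with every spot well above background on both arrays. This spread covers the spot alone and not the animal or the culture.

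The pubertal culture had higher signals for transferrin, anti-Müllerian hormone, germ cell genes and smooth muscle genes. Signals for cholesterol synthesis, glycolysis, inflammatory cytokines and early cAMP-responsive genes were lower there, relative to the other genes on the array. So were those of the metallothioneins, a family chosen after its values were seen. In all, 1042 genes were at least 2-fold higher and 900 at least 2-fold lower on the pubertal array, 13.6% of the genes measured on both. At 4-fold these numbers were 238 and 122. The median over all 14242 genes was -0.06. In simulated arrays that differed only by the noise between spots, 2 genes passed 2-fold upward and 23 downward. That noise came from replicate probes well above background on both arrays. It may be too small for dim genes, and these counts too low. Scaling on the median in place of the 75th percentile lowered every difference by 0.16 and gave 785 genes higher and 1305 lower, so that 37.6% of the calls were upward in place of 53.7%. Scaling on the spike-in control probes, an alternative chosen after the data were seen, raised every difference by 0.99 and gave 6454 genes higher and 125 lower. Directions below are therefore relative to the 75th percentile of each array, and a list median between -0.99 and 0 turns positive on the spike-in scale.

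**Figure D1:**
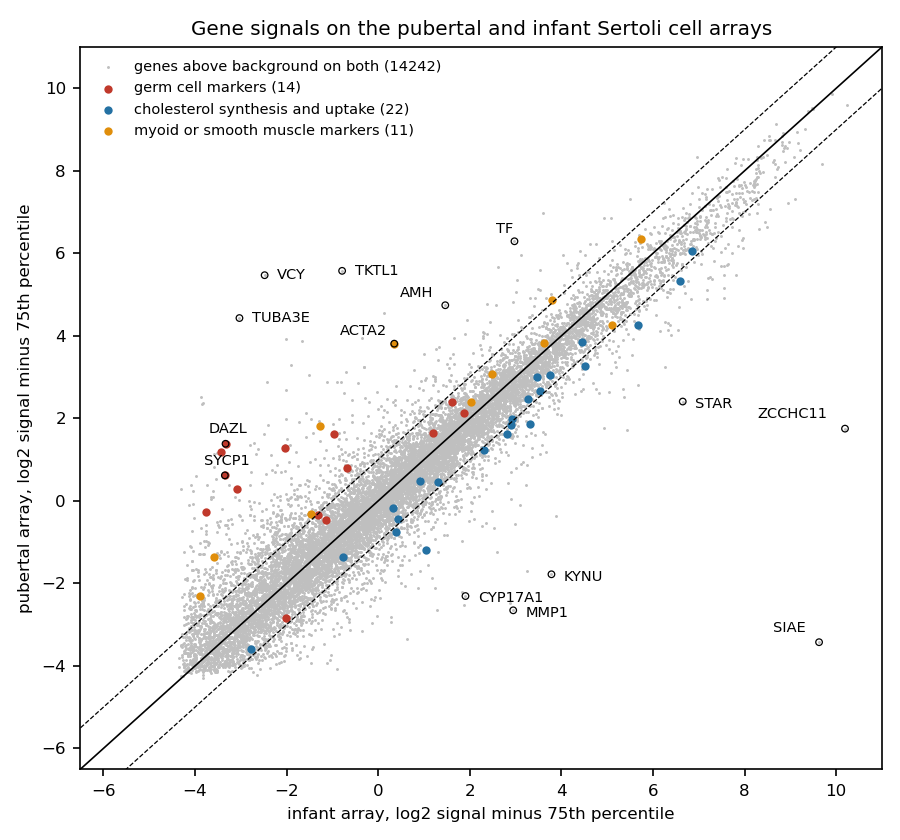
Log2 signal of 14242 genes on the infant array (x axis) and the pubertal array (y axis), each minus the 75th percentile of its array. Points are genes, coloured for germ cell (14), cholesterol (22) and smooth muscle (11) lists, with lines at equal values and at 2-fold differences; all 22 cholesterol genes lie below equality, though their median turns positive with spike-in scaling.

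The 12 largest differences toward the pubertal array included genes known from the testis beside a paraoxonase, a protease and a muscle actin. VCY, a Y-linked testis gene, was higher by 7.95 (247-fold), and TUBA3E, a testis alpha-tubulin, by 7.46. The X-linked testis genes NXF2, TKTL1, GAGE7, NXF5 and CTAG1A were higher by 6.38, 6.36, 6.20, 6.18 and 5.94. The paraoxonase PON3 (5.54), the serine protease PRSS36 (5.30), skeletal muscle actin ACTA1 (5.20), the germ cell RNA-binding protein DAZL (4.72) and the germ cell kinase STK31 (4.71) completed the 12 largest. Each of these 12 rested on 1 detected probe. VCY, GAGE7, NXF2, NXF5, CTAG1A, TUBA3E and ACTA1 belong to families with near-identical members, which a human probe on monkey RNA may not tell apart. VCY, NXF2, GAGE7, NXF5 and CTAG1A had no entry of that name in the macaque gene tables.

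Among genes lower on the pubertal array, the collagenase MMP1 differed by -5.60 (48.5-fold lower) and the tryptophan-degrading enzyme KYNU by -5.56. The protease inhibitor SLPI followed at -4.95, and skeletal myosin MYH2 at -4.41. STAR, which carries cholesterol into mitochondria for steroid synthesis, differed by -4.24 (18.9-fold lower), and the androgen-synthesis enzyme CYP17A1 by -4.21 (18.5-fold). The Wnt inhibitor DKK1 (-4.04), cardiac MYBPC3 (-3.96), the RNA-binding protein NANOS1 (-3.92) and the lipase inhibitor ANGPTL4 (-3.83) were also among the 12 largest. SIAE (-13.05) and ZCCHC11 (-8.44) had the largest values of all, but each came from 1 spot in a streak of very bright spots on the infant array. Without that spot neither was measured on both arrays. Another SIAE probe was detected on the infant array alone, at -4.11, near the lowest detected signal there.

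Another 904 genes were well above background on the pubertal array alone and 673 on the infant array alone. For such genes the fold is a lower bound, set against the higher of the dim array's lowest signal above background and the gene's own. The pubertal array alone detected the homeobox gene NKX6-2 (at least 118-fold higher), FMR1NB (at least 113-fold), GLB1L3 (at least 6.72 on the log2 scale), the X-linked homeobox gene PEPP-2 (at least 92.3-fold) and XAGE1 (at least 74.1-fold). XAGE1 is uncertain, since probes under the near-identical names XAGE1A and XAGE1B, looked up after the values were seen, were detected on the infant array alone (at least 1.70- and 1.12-fold lower on the pubertal array). The infant array alone detected the zinc transporter SLC30A2 (at least 18.5-fold lower on the pubertal array), the bradykinin receptor BDKRB2 (13.1-fold), the pseudogene EEF1DP3 (9.14-fold), TMEM47 (8.57-fold), SCFD1 (8.41-fold) and ITGB1BP3 (8.37-fold), all as lower bounds. EEF1DP3 was no longer measured without spots in disturbed areas, and of the 904 genes, 90 left the group without them.

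Most of the fixed Sertoli cell identity markers were detected in both cultures, and the defensin DEFB119, chosen here after its value was seen, on the pubertal array alone (at least 45.9-fold higher). In the list of Sertoli cell identity genes, 13 of 15 measured members had a positive difference and 4 were at least 2-fold higher on the pubertal array. Their median of 0.43 lay at the 99.6th percentile of 10000 random lists matched on expression, which describes these 2 arrays and is no test. AMH, the hormone that makes Müllerian ducts regress, was higher by 3.28 (9.69-fold), the transcription factor DMRT1 by 2.11 and the prion-like gene PRND by 1.69. The transcription factors SOX9 (0.42), WT1 (0.10) and GATA4 (-0.13) differed by less than 2-fold, as did the FSH receptor FSHR (0.79), whose signal was dim on both arrays. The only spot of SOX9 lay in an area counted as disturbed. On the scale of the median WT1 lies below 0, and on that of the spike-ins GATA4 lies above 0.

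Among 14 measured markers of immature Sertoli cells the median was 0.01 (77.6th percentile of random lists), with 2 members at least 2-fold higher and 3 lower, and the sign of this median changes with the scaling. AMH was higher, whereas podoplanin PDPN (-1.69) and keratin KRT18 (-1.24) were lower on the pubertal array. KRT18 has many near-identical pseudogenes, so its value is uncertain. Vimentin VIM differed by -0.19. The 19 measured markers of mature Sertoli cells had a median of 0.30, at the 99.3rd percentile, with 5 members at least 2-fold higher and 4 lower. Among them SOX8, CLDN11, PRND and CITED1 were also measured members of the identity list, so the high percentiles of these lists are not separate evidence. The iron carrier transferrin, TF, was higher by 3.32 (9.96-fold) with both of its measured probes, and WFDC2 by 1.91. The gap junction protein GJA1 (-1.21) and the inhibin subunit INHBB (-1.31) were lower. Clusterin CLU (0.72), claudin CLDN11 (0.26) and the dim SHBG (0.30) differed by less than 2-fold, as did INHA (-0.52) and INHBA (0.73). CYP19A1, the aromatase, was not well above background on either array.

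The genes for response to the added hormones showed a mixed picture. FSH receptor and cAMP pathway genes had a median of -0.21 over 26 members (9.08th percentile), with 2 at least 2-fold higher and 3 lower. RGS2, a brake on G protein signalling, differed by -1.80, the arrestin ARRB1 by -1.59 and the phosphodiesterase PDE4A by 1.47. Immediate cAMP response genes were lower as a group, with a median of -0.66 over 23 genes (0.02nd percentile, and 0.33 with spike-in scaling). Of these, 8 were at least 2-fold lower and 1 higher. The phosphatase DUSP1 differed by -2.86 (7.25-fold lower) and the nuclear receptors NR4A2 and NR4A3 by -2.82 and -1.50. Androgen response genes had a median of 0.11 (93.3rd percentile; 98.3rd with no filter on dim probes), which turned negative with median scaling, and 2 of 25 were at least 2-fold higher and 2 lower. The protease inhibitor SERPINA5 was higher by 1.84, while TUBB3 differed by -1.38.

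Genes that supply or instruct germ cells had a median of 0.28 over 21 members (98.2nd percentile), with 5 at least 2-fold higher and 4 lower. The retinoic acid-degrading enzyme CYP26B1 was higher by 2.44, the Notch ligand JAG2 by 2.35 and the retinoic acid-producing enzyme ALDH1A1 by 2.16. The stem cell niche factors KITLG (0.28) and GDNF (-0.39) differed by less than 2-fold. This list lay inside the central 95% of random lists with normexp background correction, with quantile normalization, with either change of the filter on dim probes and with either other way to combine probes. In the list of genes for engulfing germ cell remnants and handling lipid, 5 of 22 were at least 2-fold higher and 4 lower, with a median of 0.17 (97.2nd percentile), above the central 95% with normexp correction and among the brighter genes. The engulfment receptor MERTK (1.51) and its ligand GAS6 (1.67) were higher. FABP3, a fatty acid carrier, differed by -2.09 with 1 probe, and by 0.12 over all its probes, one of which lay in a disturbed area. Junction genes had a median of -0.20 over 32 members (11.7th percentile), with 3 at least 2-fold higher and 3 lower. E-cadherin CDH1 was higher by 1.71 and claudin CLDN4 lower, at -1.68. The probes of CTNNA1 disagreed, with a mean of 1.96, and its brighter probe gave -0.20.

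Cholesterol and glycolysis genes were lower on the pubertal array relative to the other genes. All 22 measured genes of cholesterol synthesis and uptake had a negative difference, and 9 were at least 2-fold lower. Their median was -0.87, below all 10000 random lists, and 0.12 with spike-in scaling. INSIG1, a sterol sensor, differed by -2.23 (4.68-fold lower), the mevalonate pathway enzymes MVD by -1.47 and FDPS by -1.41. The only spot of MVD lay in an area counted as disturbed. In glucose uptake, glycolysis and lactate release, by which Sertoli cells feed germ cells, 24 of 28 genes had a negative difference, 5 of them at least 2-fold and none 2-fold higher. The median was -0.66, also below all random lists, and 0.33 with spike-in scaling. The lactate exporter SLC16A3 differed by -1.58, pyruvate kinase PKM2 by -1.36 and the glucose transporter SLC2A1 by -1.32. Respiratory chain genes had a median of -0.18 (47.9th percentile), which turned positive with quantile normalization, with none past 2-fold and COX5A at -0.94, NDUFA9 at -0.71 and UQCRFS1 at -0.61. Ribosomal protein genes had a median of -0.48 (3.18th percentile), with 36 of 37 negative but none by 2-fold, RPL4 being lowest at -0.99, ahead of RPS18 (-0.87) and RPL10 (-0.83). With either change of the filter on dim probes this list lay below the central 95% of random lists.

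Steroid-producing genes moved apart. The 18 measured members had a median of -0.17 (29.5th percentile), which turned positive with quantile and loess normalization, with 3 at least 2-fold lower and 1 higher. STAR and CYP17A1 were lower by the sizes given above, whereas NR0B1, a repressor of steroid synthesis, was higher by 1.82 (3.54-fold). Insulin and IGF genes had a median of 0.12 over 23 members (90.4th percentile), with the binding proteins IGFBP4 (-1.77), IGFBP3 (-1.28) and IGFBP7 (-1.05) at least 2-fold lower. This median too turned negative with median scaling.

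Inflammatory, oxidative stress and interferon response genes were lower on the pubertal array relative to the other genes, and antigen presentation and heat shock genes were not. Of 15 measured cytokine and chemokine genes, 9 were at least 2-fold lower and none 2-fold higher, and the median of -1.07 lay below all 10000 random lists, at -0.08 with spike-in scaling. IL6 differed by -2.48 (5.59-fold lower), the superoxide dismutase SOD2 by -2.19 and the alarmin IL33 by -1.85. Hypoxia and oxidative stress genes had a median of -0.67 over 22 members, below all random lists, and 0.32 with spike-in scaling, with 6 at least 2-fold lower and 1 higher. Haem oxygenase HMOX1 differed by -2.40 and the metallothioneins MT1X and MT1E by -2.36 and -2.27. Interferon response genes had a median of -0.36 over 23 members (1.14th percentile, and 0.63 with spike-in scaling), with 4 at least 2-fold lower and 3 higher. The antiviral tether BST2 differed by -3.19, while HERC5 was higher by 1.87. With the brightest probe of each gene this list lay inside the central 95% of random lists. Antigen presentation genes had a median of -0.15 (40.3rd percentile) with none past 2-fold, PSMB8 being at 0.90 and HLA-E at -0.61. Heat shock and unfolded protein genes had a median of -0.09 (69.8th percentile), which turned positive with quantile and loess normalization, with TRIB3 at -1.82, PDIA4 at -1.15 and HSPA6 at 1.03.

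Signalling lists held single genes with large differences in both directions. Wnt genes had a median of 0.25 over 30 members (98.99th percentile), with 8 at least 2-fold higher and 1, DKK1, lower. The Wnt effector LEF1 was higher by 2.69 (6.46-fold) and the receptor FZD1 by 1.78. Among the 13 brighter of these genes the median was -0.25, and with no filter on dim probes the list lay inside the central 95% of random lists. Notch genes had a median of -0.04 over 19 members (52.3rd percentile), whose sign turned with the scaling, with 3 at least 2-fold higher and 2 lower. HEY2, a Notch target, was higher by 2.96, the ligand DLL1 by 2.47 with all 3 probes, and JAG2 by 2.35. In the TGF-beta, BMP and activin list the median was -0.04 over 35 members (58.7th percentile), whose sign also turned with the scaling, with 4 at least 2-fold higher and 4 lower. ID4, a helix-loop-helix inhibitor that was also a fixed germ cell marker, was higher by 3.31. GDF15, a stress-induced cytokine, differed by -3.71 (13.1-fold lower). Thyroid hormone and retinoid genes had a median of -0.15 (25.6th percentile), with 2 at least 2-fold higher and 2 lower. CYP26B1 (2.44) and ALDH1A1 (2.16), given above, had the largest differences, and KLF9 differed by -1.11. HOX and patterning genes had a median of -0.26 over 14 members (9.14th percentile), with HOXC9 at 1.80, HOXD10 at -1.78 and NR2F1 at -1.15.

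Secreted proteins, proteases and inhibitors spread widely, with 7 of 26 at least 2-fold higher and 8 lower. Their median of 0.10 lay at the 97.6th percentile of random lists, and was -0.06 with median scaling. It lay inside the central 95% with normexp correction, quantile normalization, the brightest probe or no disturbed areas. TF stood at one end and MMP1 at the other, with the protease inhibitor TIMP3 at -2.49. Matrix and basement membrane genes had a median of 0.11 over 37 members (93.8th percentile), which turned negative with median scaling. It lay above the central 95% of random lists, up to the 99.2nd percentile, with normexp correction, quantile normalization, no disturbed areas, no filter on dim probes or the brightest probe. The fibulin FBLN2 (2.06) and collagen COL1A2 (1.92) were higher and the nidogen NID2 (-1.73) lower. Cell cycle genes had a median of -0.14 over 40 members (16.4th percentile), with 4 at least 2-fold lower and none higher. TYMS and RRM2, which make DNA precursors, differed by -1.19 and -1.07, and the mitotic kinesin KIF20A by -1.11. Cell cycle inhibitors and p53 targets had a median of -0.21 (13.2nd percentile; 2.43rd with the median of all probes), with FAS at -1.37, CDKN1B at 1.03 and MDM2 at -0.92. Housekeeping genes had a median of -0.34 over 17 members (20.8th percentile), with POLR2A at 1.22, RPLP0 at -0.73 and PGK1 at -0.69.

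**Figure D2:**
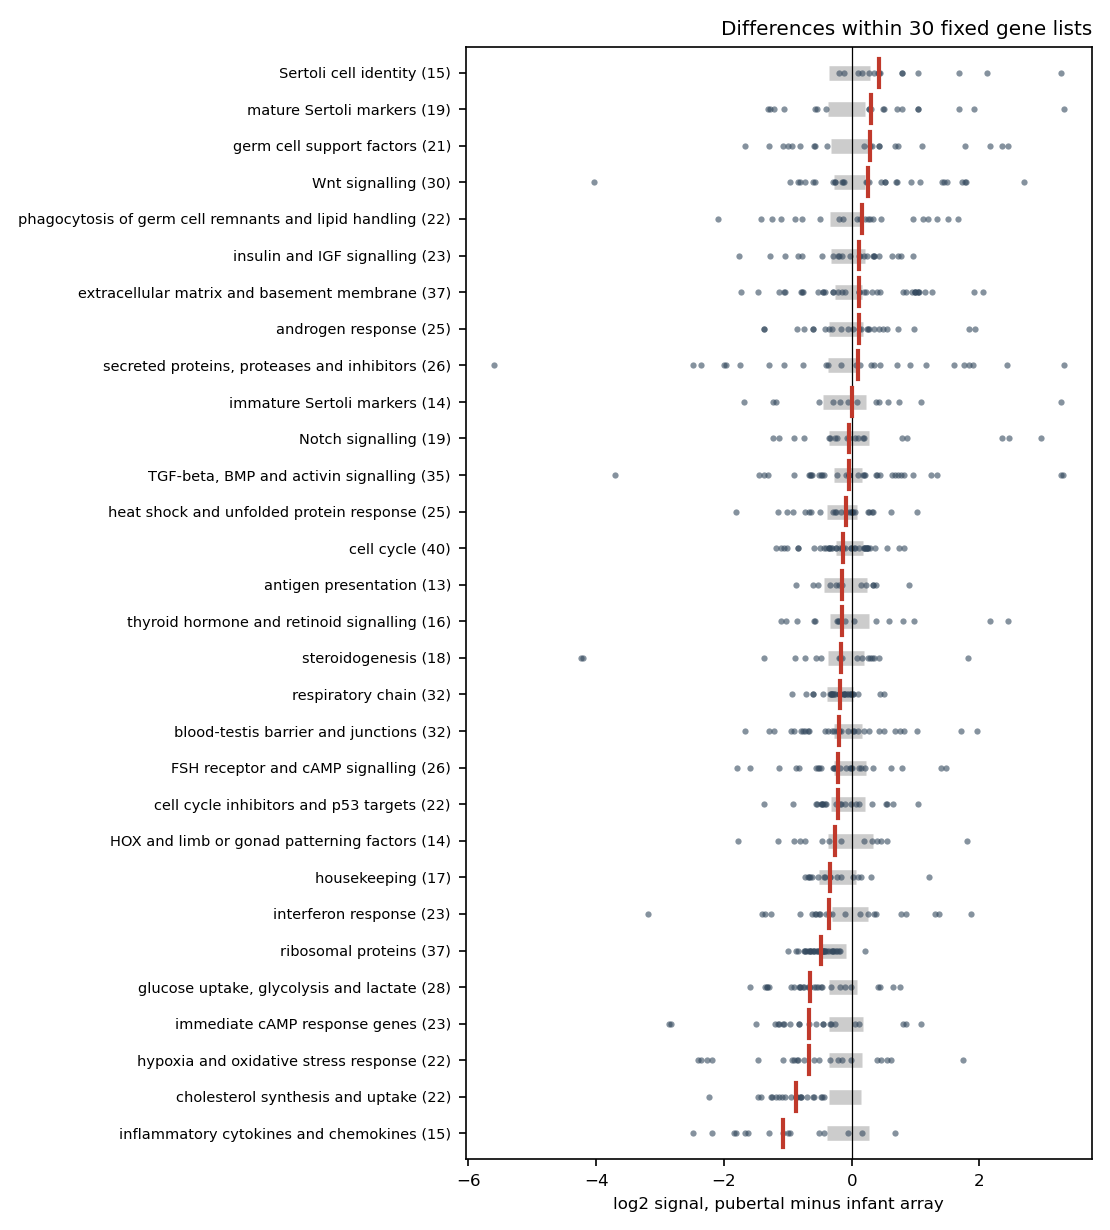
Log2 difference (pubertal minus infant array, x axis) of each measured member of 30 gene lists (rows, with the number of measured members). Points are genes, red bars are medians, from 0.43 (Sertoli cell identity) to -1.07 (inflammatory genes), and grey bands hold the central 95% of medians of 10000 random lists; spike-in scaling adds 0.99 to all, which turns each negative median but the inflammatory one positive, and median scaling moves all to the left by 0.16.

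Markers of other cells that a testis culture can hold differed strongly for some cell types and not for others. Germ cell markers stood furthest apart. Of 10 markers of undifferentiated germ cells above background on both arrays, 5 were at least 2-fold higher on the pubertal array and none lower, with a median of 1.23 that exceeded all 10000 random lists. A further 11 were detected on the pubertal array alone and none on the infant array alone. Among the brighter genes alone this list lay inside the central 95% of random lists. DAZL, FGFR3 and MAEL were higher by 4.72, 4.62 and 3.37, corresponding to 26.3-, 24.6- and 10.3-fold. Among markers of meiotic or haploid germ cells, 4 were measured on both arrays, with a median of 3.04 that also exceeded all random lists, and 6 were detected on the pubertal array alone. With no filter on dim probes, which brings in genes detected on neither array, this median was 0.66. The synaptonemal complex protein SYCP1 was higher by 3.97 (15.6-fold), the surface protein TEX101 by 3.48 and the germ cell lactate dehydrogenase LDHC was 6.06-fold higher. Another 13 markers of that list, the protamine and transition protein genes of spermatids among them, were above background on neither array.

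Of 11 peritubular myoid or smooth muscle markers, 6 were at least 2-fold higher and none lower, with a median of 1.07 above all random lists. Smooth muscle actin ACTA2 was higher by 3.46, ACTG2 by 3.10 and the myosin MYH11 by 2.24. The actin genes are near-identical, so their single values are uncertain. The median was 0.96 over 8 macrophage markers (99.96th percentile), with the scavenger receptor CD163 higher by 3.08 (8.49-fold), CSF1R by 2.07 and PTPRC by 1.99. It was 0.83 over 6 endothelial markers (99.5th percentile), with PECAM1 at 1.43, EGFL7 at 1.40 and VWF at 0.99. It was 1.03 over 6 neural or Schwann markers (99.9th percentile), with S100B higher by 1.35. Without a filter on dim probes the neural list lay inside the central 95% of random lists.

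The remaining cell type lists lay inside that range with the settings used throughout. The 8 Leydig cell markers had a median of 0.27 (95.7th percentile), with STAR, CYP17A1 and CYP11A1 (-1.37) lower and 5 others above 0 but under 2-fold, up to 0.56 for DLK1. Fibroblast markers had a median of -0.15 over 8 genes (33.1st percentile), with COL1A2 higher, DCN (-1.49) lower and FBLN1 at 0.98. The median was -0.55 over 5 pericyte markers (3.65th percentile; 2.14th with normexp correction), although RGS5 was higher by 2.23, with NOTCH3 at -1.14 and CSPG4 at -1.02. It was -0.26 over 5 lymphocyte or mast cell markers (19.8th percentile; CD3E -0.63, CD8A -0.51) and -0.23 over 5 red blood cell markers (21.2nd percentile; HBA1 -1.12, HBA2 0.49, HBG2 -0.35). Epithelial markers had a median of -0.04 over 5 genes (47.6th percentile), with SLPI lower and WFDC2 and CDH1 higher, and the median was 1.71 with no filter on dim probes and -1.41 with the filter at the median signal, outside the range in both cases. All these negative medians turn positive with spike-in scaling.

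**Figure D3:**
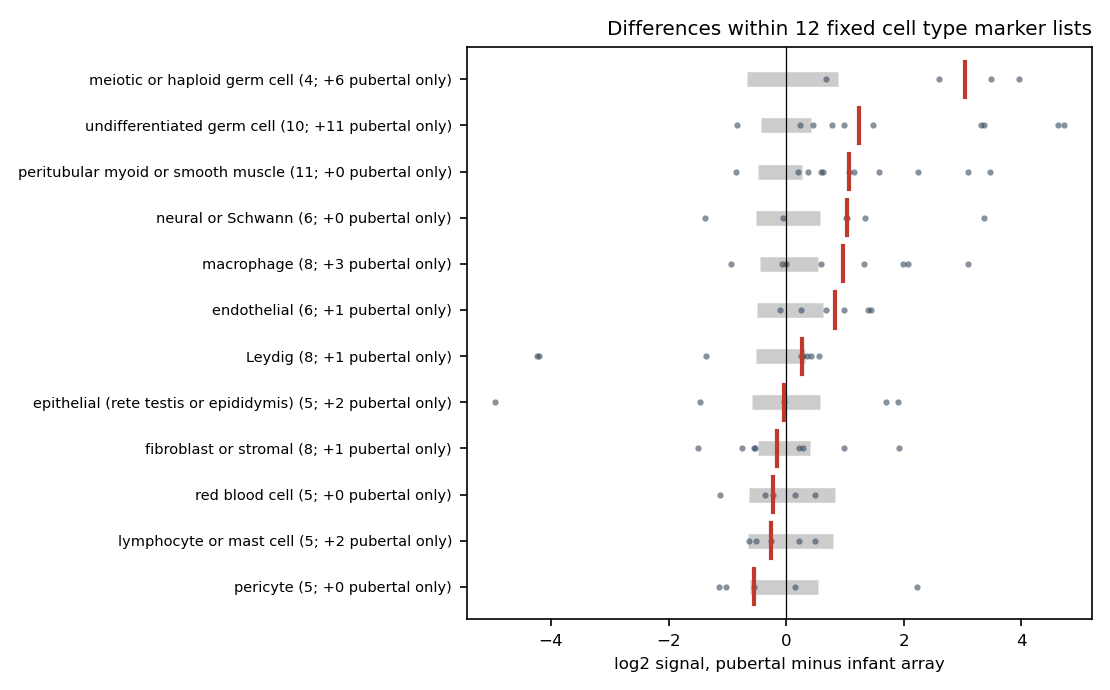
Log2 difference (pubertal minus infant array, x axis) of each measured marker in 12 cell type lists (rows, with the number measured on both arrays and the number detected on the pubertal array alone). Points are genes, red bars are medians, among them 3.04 and 1.23 for meiotic and undifferentiated germ cells and -0.15 for fibroblasts, and grey bands hold the central 95% of medians of 10000 random lists; spike-in scaling adds 0.99 to all, which turns the negative medians positive.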

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

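The tests on disturbed areas, on cell shares, on germ cells, on Leydig markers and on the streak, and the spike-in scaling, were chosen only after the results were seen, the one on cell shares as the last of several forms; the loess test was planned. No group had enough arrays to look for outlying samples.

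Signals outside the gene comparison drew attention. The spike-in control probes differed by -0.99 on average after the 75th percentile scaling, over 7 probes of 35 spots each, ranging from -1.23 to -0.72. Of 308 negative control spots, 3 were above background on the pubertal array, all in an area of raised signal, against 2 on the infant array outside it. Among 5035 probes without a gene name and above background on both arrays, 321 were at least 2-fold higher and 305 at least 2-fold lower on the pubertal array.

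The first pattern is the germ cell signal of the pubertal culture, where 25 of 31 detected markers (80.6%) were at least 2-fold higher or detected there alone; of the 48 fixed, 3 belong to another list too. Without spots in disturbed areas 100% of the 25 kept that status, which argues against raised signal in those areas as the cause. Outside the area of raised signal, 0 of 305 negative control spots were above background on the pubertal array and 2 on the infant array. False detection there was thus not more common on the pubertal array. Raised background over the rest of the array was not tested further. If a lower share of Sertoli cells raised all other cell types alike, germ cell and other markers would rise alike. The median of 14 germ cell markers lay 1.75 above that of 66 markers of the other 10 cell types (95% bootstrap interval over markers 0.30 to 3.23). Among markers with an infant signal below the array's 75th percentile the gap was 2.76 (0.38 to 3.48), though a low infant signal itself favours a high difference. These gaps argue against an equal rise of all other cell types. Markers that Sertoli cells also express would rise less, so the test cannot judge a lower share with unequal rises, which stays open. Smooth muscle (1.07), neural (1.03), macrophage (0.96) and endothelial (0.83) medians were higher too, and Sertoli identity (0.43) was not lower. Pericyte (-0.55), lymphocyte (-0.26), red blood cell (-0.23) and fibroblast (-0.15) medians were not raised. Germ cells carried in the pubertal culture may be the source and stay open; the markers with the highest signals there were DND1 (2.40), UTF1 (2.13), TCF3 (1.64) and LDHC (1.62), with differences of 0.78, 0.24 and 0.45 and, for LDHC, 6.06-fold, and signals of different probes cannot be ranked as amounts, while a difference within Sertoli cells with age or puberty stays open too, untested, since each group had 1 culture.

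The next pattern pairs low STAR and CYP17A1 with low cholesterol synthesis genes. Fewer Leydig cells in the pubertal culture would lower all markers that Leydig cells alone express. The other 6 measured Leydig markers had a median of 0.32. Of these, 5 lay above 0, up to 0.56 for DLK1, while CYP11A1 was lower too, at -1.37. DLK1 was also a fixed marker of immature Sertoli cells, and markers that other cells express need not fall. The test therefore cannot decide on fewer Leydig cells, which stay open. With the loess of difference on signal strength removed, the cholesterol median moved only from -0.87 to -0.81. That argues against such a trend as the main source. The list stayed below all 10000 random lists. These were matched on mean signal, so removing the trend could hardly change that position, which adds no support. Spike-in scaling moves all genes alike, so its cholesterol median of 0.12 leaves the list below all random lists by construction: a uniform difference in RNA or spike-in amount cannot account for that position, and only the absolute direction is unsettled. Age, puberty and the response to the hormones stay open and untested, since no untreated culture was among the arrays.

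The last pattern is the extreme value of SIAE and ZCCHC11. Their spots lay in a streak on the infant array, where 13 of 37 neighbouring spots (35.1%) were lower by over 4 log2 on the pubertal array, against 0.127% of all spots. Bright debris is a candidate cause, and no biological explanation was tested.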

How the results depend on the processing

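Spike-in scaling and the disturbed areas were chosen after the data were seen; other alternatives were fixed beforehand. The numbers of genes higher and lower, 1042 and 900, were 553 and 568 with normexp correction, 2080 and 1485 with no filter on dim probes, 376 and 498 with the filter at the median signal, 2141 and 2392 with a 1.5-fold threshold, 238 and 122 with a 4-fold threshold, and 6454 and 125 with spike-in scaling. By construction, the normexp offset shrinks differences of dim genes, the filters change how many genes are compared, and spike-in scaling adds 0.99 to each difference; causes beyond this were not tested. The other counts stayed within 1.5 times. Genes detected on the infant array alone numbered 1036 in place of 673 with the weaker detection flag; those on the pubertal array alone numbered 965 and 904, and 815 without disturbed areas. Of 17 lists outside the central 95% of random lists, 11 stayed outside on the same side under every alternative run. The germ cell support, secreted protein, Wnt, interferon, undifferentiated germ cell and neural lists did not. The androgen, p53, matrix, phagocytosis, ribosomal, pericyte and epithelial lists, inside that range, left it under some alternative. Median scaling, the percentile over detected probes alone and spike-in scaling each shift all differences by a constant. They cannot change a list's percentile or the gap between cell type markers given below, so only the other alternatives bear on these. Loess normalization removes a trend with mean signal that the matched random lists share, so it can hardly change a percentile either. The lowest medians over the alternatives were 0.66 for meiotic germ cells, 0.48 for undifferentiated germ cells, 0.60 for smooth muscle, 0.59 for endothelial, 0.55 for macrophage and 0.22 for neural markers. The epithelial median ran from -1.41 to 1.71. The gap between germ cell and other cell type markers, 1.75, had an interval above 0 in each alternative over all markers, and was 0.36 with the filter at the median signal, where 4 germ cell markers were left. Among markers with an infant signal below the array's 75th percentile the gap was 2.76 (0.38 to 3.48). With the filter at the median signal, which left 1 such germ cell marker, it was -0.02, and the interval from -0.70 to 3.47 held 0.

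Among lists outside the range and genes past 2-fold, signs turned in the following cases, and the cause was not tested beyond the shift of scale; many medians nearer 0 turned too. The secreted protein median was -0.0059 with normexp and -0.061 with median scaling, and the Wnt median -0.25 with the filter at the median signal. With spike-in scaling the medians were 0.33 for immediate cAMP response genes, 0.33 for glycolysis, 0.12 for cholesterol, 0.63 for interferon and 0.32 for oxidative stress genes, with percentiles unchanged at 0.02, 0, 0, 1.14 and 0, since this scaling moves all genes alike. CTNNA1 was at -0.20 with its brightest probe and with the filter at the median signal, and FABP3 at 0.12 with no filter and with the median of all probes. Of 114 named genes at least 2-fold different, the other 112 kept their direction under every alternative that gave a value, and 70 of the 114 stayed at least 2-fold different under all of these. Signal over background limits FSHR, SHBG, NR4A2, NXF2, NXF5 and GAGE7, among others, which lay near the lowest detected signal on at least 1 array.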

Other observations

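Gene families in this part were chosen after their values were seen, so their counts describe these 2 arrays and are no independent evidence. A set of 64 X-linked genes on the array was taken, mostly cancer/testis antigens, which tumours share with the testis. It included TKTL1, a transketolase-like gene, and the RNA export factors NXF2 and NXF5. Of the 64, 14 were measured on both arrays and 13 of them were at least 2-fold higher on the pubertal array, with a median of 4.50. Another 28 were detected on the pubertal array alone and 5 on the infant array alone, and 26 of the 28 remained without spots in disturbed areas. Many of these genes have near-identical family members, so their single names are uncertain, and MAGEA4 was also a fixed germ cell marker. Of 26 genes of the piRNA pathway, which silences transposons in germ cells, and of meiosis, 7 of 11 measured were at least 2-fold higher and 10 more were detected on the pubertal array alone. Of these genes MAEL, HORMAD1, PIWIL2 and PIWIL4 were also fixed germ cell markers. The cohesin subunit STAG3 was higher by 3.78, the helicase DDX43 by 4.01 and SPATA22 by 4.25, and PIWIL4 and TDRD9 were at least 26.7- and 23.5-fold higher.

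Metallothioneins, which bind zinc and copper, were lower as a family. All 9 measured members had a negative difference and 7 were at least 2-fold lower, with a median of -2.19, which stayed negative at -1.20 with spike-in scaling. MT2A (-0.83, with probes of opposite sign) and MT3 (-0.39) differed least and turn positive on that scale, and these genes too are hard to tell apart. MT1X, MT1E and MT2A were also members of the fixed hypoxia and oxidative stress list, so the results for the family and that list overlap. All 5 alpha-class glutathione S-transferases, detoxifying enzymes whose genes are near-identical, had a positive difference, 4 of them at least 2-fold, with GSTA5 at 1.78 and GSTA2 at 1.46. In the protocadherin beta cluster all 10 measured genes had a positive difference, 5 of them at least 2-fold, with a median of 1.03 that was 0.66 after normexp correction. The medians of these 3 families kept their direction under every scaling run. Of 16 measured keratins, 2 were at least 2-fold lower and none higher, with a median of -0.02 whose sign turns with the scaling.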
